A study of Mus musculus with 12 samples.

How the data were processed

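Transcript levels were measured in whole liver of ovariectomized female mice, 3 months old and labelled C57BL/6, on the Affymetrix Mouse Gene 1.0 ST array, a whole-transcript array of oligonucleotide probes. The mice were wild type, per the labels ERKO (no oestrogen receptor alpha) or MOER (oestrogen receptor alpha at the cell membrane alone). After 1 week of recovery they received PPT, an agonist selective for oestrogen receptor alpha, at 100 µg per day, or 0.1 mL of oil, for 3 days. The RNA of 3 animals was pooled for an array, and the labels say that the experiment was done again, which gives 6 groups of 2 arrays and 12 arrays in all. The labels do not show that the 2 arrays of a group came from separate animals or pools, so each p-value measures only the spread between these arrays.

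The deposited table gave 1 value per probe set and array as linear hybridisation intensity, with 28815 probe sets and 345780 values, of which 389 were 0. The medians of the 12 arrays lay between 77.5 and 85.26, so the values were taken as already on a common scale and were not normalised again. How the authors summarised probes and normalised arrays is not given in the sources used here. Per the labels the authors used the program Cyber-T at 99.99% confidence with a change of at least 2-fold, and sought transcripts that PPT changed in wild type and MOER livers but not in ERKO livers. Of all values, 2 exceeded 65535, the largest number a 16-bit scanner gives, both for an amylase probe set with several gene symbols in the MOER oil arrays, 1602759 in replicate 1 and 1219897 in replicate 2.

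The platform's annotation gave 1 gene symbol for 21780 probe sets, several for 1605 and none for 5430. Of the probe sets with 1 symbol, 21689 had an Entrez ID in the RefSeq table of assembly GRCm38.p6, which was used for names and gene order only, so no coordinates are given, and 0 symbols needed updating. Some genes fixed in advance are not reported here.

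Intensities were transformed as log2(intensity + 16). Probe sets above the 40th percentile of their own array in at least 2 of the 12 arrays were tested, 19119 in all, of which 15226 had 1 symbol, 1025 several and 2868 none. Greb1, an oestrogen-responsive gene, did not pass this filter. A gene was represented by its probe set of highest mean, which left 13987 genes. Among 707 genes with several probe sets, probe sets of 1 gene were called in opposite directions for 3 genes in wild type, 1 in MOER and 2 in ERKO.

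All 12 arrays entered 1 limma fit of 6 group means (lmFit and eBayes without trend, limma 3.58.1 in R 4.3.3), with 6 residual degrees of freedom and 10.47 after moderation. The 10 contrasts were the PPT response within each genotype, the 3 differences between those responses, the 3 differences between genotypes under oil, and the mean of the wild type and MOER responses minus the ERKO response. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 19119 probe sets, and a probe set was called at an adjusted p under 0.05. No detection calls are in the deposited table. Chosen after seeing the data, a group was taken as dim for a probe set where both arrays lay under their own 40th percentile, which was 53.576 to 60.98. A log2 change into or out of a dim group depends on the added 16, and its size and rank are not measured. Where 1 of 2 groups was dim, the text gives the fold of the brighter group over the dim one, with the dim arrays at no less than their 40th percentile, as at least that fold. List medians keep the fitted values. Errors of log2 changes are the standard errors of the fit, and errors of intensities are standard deviations of 2 arrays.

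There were 28 gene lists, 17 of pathways and 11 of cell types, with 491 symbols of which 1 could not be resolved. The pathway lists were cholesterol synthesis, fatty acid synthesis, triglyceride synthesis and lipid droplets, fatty acid oxidation and PPAR-alpha targets, bile acid and sterol disposal, gluconeogenesis and insulin-regulated genes, oestrogen-responsive genes, male-biased and female-biased liver genes, acute phase proteins, interferon-induced genes, the unfolded protein and amino acid stress response, drug metabolism, cell cycle, circadian clock, immediate early and heat shock genes as a sign of handling, and oxidative phosphorylation. The cell type lists were macrophages and Kupffer cells, lymphocytes, neutrophils, red blood cell precursors, endothelial cells, stellate cells and fibroblasts, bile duct cells, adipocytes, pancreatic acinar cells, and pericentral and periportal hepatocytes. Each list was tested with camera at a preset correlation of 0.01 and adjusted over the 28 lists of a contrast, then again with a correlation estimated from the data, and with fry. With the estimated correlation 1 list was called in the MOER response, 1 in MOER minus ERKO, 2 in wild type minus MOER, 1 in each of the 2 comparisons of MOER under oil, and 0 in the other contrasts. Every other camera call below holds with the preset correlation alone. By fry, which asks whether the genes of a list move at all in 1 direction, 22 lists were called in wild type, 18 in MOER and 21 in ERKO, against 15, 16 and 18 by camera at the preset correlation. A further 6 lists were written after transcripts of other tissues and a shift of clock genes had been seen: skeletal muscle, stratified epithelium and lung epithelium markers, hepatocyte secretory genes, and clock genes of the Arntl phase and of the Dbp phase.

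The contrasts, tests, 28 lists, alternatives and the rule for named genes were set before the data were examined. The rule takes, in each PPT response and in ERKO and MOER against wild type under oil, the 8 called genes with the largest rise and the 8 with the largest fall whose arrays do not overlap, up to 4 members of each list by smallest p, the 8 genes with the largest mean change called in wild type and MOER with 1 sign and not in ERKO, the 5 largest genes of each difference of responses, and Esr1, Srebf1, Fasn, Acaca, Scd1, Cyp7a1, Igf1 and Cish. Some genes were added to these after their values were seen and are named as such where they appear, and the text gives a selection of the genes the rule names.

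The fit was tested on simulated data of the same size for the wild type response, with 200 changed probe sets among 19119, 50 per fold size. It recovered 4% of those changed 1.25-fold, 56% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, and 7.46% of its calls were false. A Cyber-T-style test with a 2-fold minimum recovered 58% at 2-fold and 100% at 4-fold. For an ERKO response simulated without any change, 0 probe sets were called. This 0 does not bound false calls among the 3430 in ERKO, a count that depends on the spread used (576 with the ERKO arrays alone). Wild type had 5921 calls, so recovery among 200 simulated changes may not carry over.

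The alternatives were no filter, a 60th percentile filter, quantile normalisation, median centring of each array, pseudocounts of 1 and 64, eBayes with trend and robust, a fit of the compared arrays alone, a replicate block, a 2-fold minimum, a Cyber-T-style test (window of 101 probe sets, prior weight 10, p under 0.0001 and 2-fold), and leaving out each array. A restriction to probe sets expressed in wild type liver, and a block with the MOER PPT numbers crossed, were chosen after seeing the data. Replicate numbers were not used to pair arrays, since over the 15 pairs of groups the deviations of equally numbered arrays correlated between -0.147 and 0.377, with 5 pairs above 0.1. All 3 pairs of oil groups were among the 5 (wild type with ERKO 0.276, wild type with MOER 0.354, ERKO with MOER 0.377), so equally numbered oil arrays deviated together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.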

Results

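Liver transcripts were profiled on 12 arrays, 2 for each of 6 groups: wild type, ERKO and MOER mice, each given oil or PPT. Of 28815 probe sets, 19119 were bright enough to test, and the median intensity of an array lay between 77.5 and 85.26. The 2 arrays of a group correlated at 0.994 to 0.996 (Pearson's r across probe sets, which are not independent replicates), except in ERKO oil, where r was 0.981 and 162 probe sets differed by more than 2-fold between the arrays. The first 2 principal components held 40.6% and 22.3% of the variance. The labels and the study's title pose the question whether the agonist's effect on liver lipid genes comes from the receptor at the membrane, which per the labels MOER livers have and ERKO livers lack.

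Esr1, the gene of oestrogen receptor alpha (probe set 10367600), gave 356 ± 12.6 in wild type oil arrays and 317 ± 11.6 after PPT (mean intensity ± SD, n = 2). In ERKO it gave 122 ± 5.62 under oil and 154 ± 11.3 under PPT, and in MOER 127 ± 0.926 and 124 ± 10.01. Under oil Esr1 was thus lower than in wild type by a log2 difference of -1.43 ± 0.093 in ERKO (limma, Benjamini-Hochberg adjusted p = 1.43e-05) and -1.38 ± 0.093 in MOER (adjusted p = 1.06e-05). MOER minus ERKO was 0.05 ± 0.093 (adjusted p = 0.816). The probe set was thus not shown to read more in MOER than in ERKO, and it does not check the MOER label against ERKO. Which part of the transcript it covers was not tested, and the receptor protein was not measured. The rise of Esr1 with PPT in ERKO, 0.30 (adjusted p = 0.0496), was lost in 11 of 12 leave-one-out fits, with the replicate block, with the trended fit and under median centring, where it was 0.25.

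**Figure D1:**
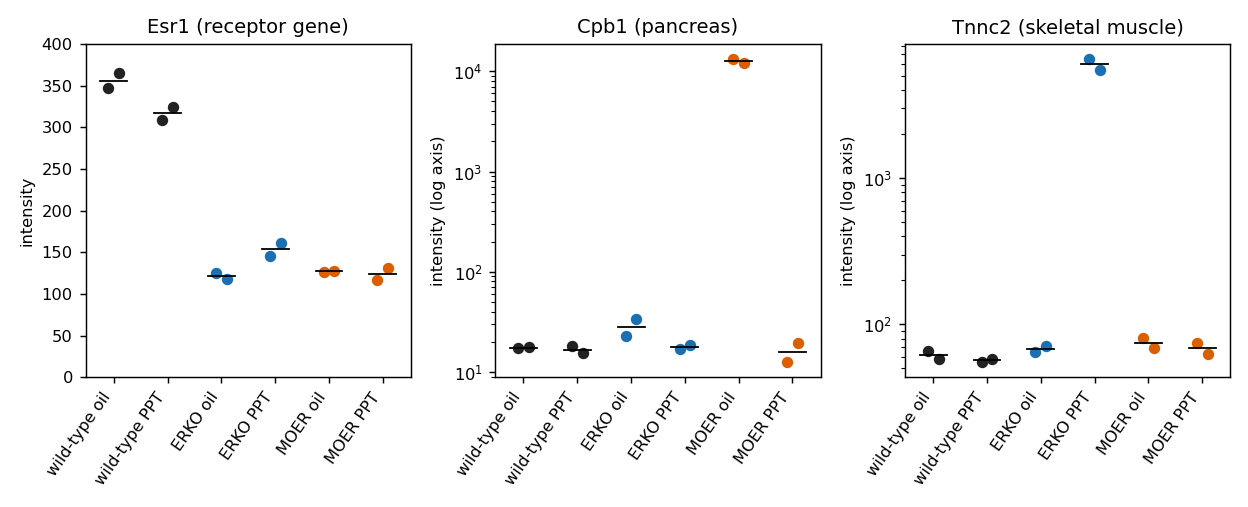
Intensity of Esr1 (linear axis), of the pancreatic gene Cpb1 and of the skeletal muscle gene Tnnc2 (log axes) on each of the 12 arrays, points for arrays and lines for group means. Cpb1 averaged 12634 in MOER oil and Tnnc2 5999 in ERKO PPT, against means of at most 28.4 and 74.9 in the other groups.

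The first comparison asked what the agonist changes where the receptor is intact. In wild type livers PPT lowered genes of sterol and lipid synthesis and of bile acid synthesis. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (probe set 10511375), fell from 2588 ± 48.8 to 21.7 ± 1.32 (n = 2), at least 46.3-fold (adjusted p = 4.34e-11). Cyp8b1, the sterol 12-alpha-hydroxylase, fell from 594 ± 16.4 to 16.4 ± 0.552, at least 10.6-fold, and Car3, a carbonic anhydrase, from 11034 ± 290.1 to 644 ± 3.2. Srebf1, which encodes the transcription factor SREBP-1 (probe set 10386473), fell by 1.38 on the log2 scale (adjusted p = 8.23e-06), and the fatty acid synthase gene Fasn (probe set 10393970) from 536 ± 7.17 to 352 ± 21.1, -0.59 ± 0.099 on the log2 scale.

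In the cholesterol synthesis list 0 of 20 measured genes rose and 19 fell (0 and 19 adjusted over the list alone). The cholesterol synthesis median was -1.16, with a camera adjusted p of 6.6e-15 (adjusted p = 0.204 with an estimated correlation). Nsdhl (-2.09 ± 0.082), Dhcr7 (-1.60 ± 0.082), Fdft1 (-1.61 ± 0.087) and Insig1 (-1.68 ± 0.10), which retains SREBP in the endoplasmic reticulum, had the smallest p. Hmgcs1 was the 1 member not called, at 0.18 ± 0.087. In the fatty acid synthesis list 1 of 18 measured genes rose and 15 fell (1 and 15 adjusted over the list alone). The fatty acid synthesis median was -1.01, with a camera adjusted p of 3.85e-09 (adjusted p = 0.204 with an estimated correlation). The acetyl-CoA synthetase gene Acss2 fell from 1744 ± 30.3 to 201 ± 12.2 and the desaturase gene Scd1 from 7790.4 ± 166 to 2322 ± 121, Acaca changed by -0.59 ± 0.093, and Thrsp, a gene induced with lipogenesis, rose from 2585 ± 30.8 to 7174 ± 178. In the bile acid and sterol disposal list 5 of 17 measured genes rose and 12 fell (5 and 12 adjusted over the list alone). The bile acid median was -0.96, with a camera adjusted p of 2.48e-05 (adjusted p = 0.414 with an estimated correlation). Cyp7b1 rose by 3.19 ± 0.098. In the fatty acid oxidation and PPAR-alpha target list 2 of 23 measured genes rose and 14 fell (2 and 16 adjusted over the list alone). The oxidation median was -0.46, with a camera adjusted p of 1.56e-05 (adjusted p = 0.414 with an estimated correlation). Acot3 fell at least 8.31-fold and Ehhadh rose by 2.40. Over the same arrays, 16 genes of secreted hepatocyte proteins had a median log2 change of -0.43, with 12 called.

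PPT raised in wild type Slc34a2, a sodium-phosphate cotransporter, from 24.3 ± 2.18 to 8500.2 ± 238 (at least 158-fold), Krt4, a keratin of stratified epithelia, from 11.5 ± 10.3 to 3259 ± 69.4 (at least 60.5-fold), and Prtn3, a neutrophil serine protease, from 60.7 ± 8.48 to 3605 ± 41.2. Akr1c18, which inactivates progesterone, rose by 5.17 ± 0.13 and the lipid droplet gene Cidec at least 9.08-fold. In the unfolded protein and amino acid stress response list 13 of 15 measured genes rose and 0 fell (13 and 0 adjusted over the list alone). The stress response median was 1.29, with a camera adjusted p of 6.43e-11 (adjusted p = 0.156 with an estimated correlation). Sdf2l1 rose by 2.18 ± 0.097 and Manf by 2.00 ± 0.090. In the cell cycle list 13 of 20 measured genes rose and 0 fell (14 and 0 adjusted over the list alone). The cell cycle median was 0.71, with a camera adjusted p of 6.17e-07 (adjusted p = 0.0566 with an estimated correlation). Top2a rose by 1.24 ± 0.10. In the oestrogen-responsive list 6 of 15 measured genes rose and 4 fell (6 and 4 adjusted over the list alone). The oestrogen list median was 0.05, with a camera adjusted p of 0.405. Lifr rose from 1784 ± 13.7 to 11434 ± 103, Myc by 1.90 ± 0.13 and Ccnd1 by 1.01 ± 0.090. Igf1 changed by -0.43 (adjusted p = 0.00275), and Cish by 0.05 without passing the test (adjusted p = 0.823).

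Markers of other functions and cell types also moved in wild type. In the drug metabolism list 0 of 11 measured genes rose and 9 fell (1 and 9 adjusted over the list alone). The drug metabolism median was -0.98, with a camera adjusted p of 5.18e-06 (adjusted p = 0.382 with an estimated correlation). Cyp2b10 changed by -3.78 ± 0.092. In the female-biased list 4 of 19 measured genes rose and 12 fell (4 and 12 adjusted over the list alone). The female-biased median was -0.87, with a camera adjusted p of 2.87e-04 (adjusted p = 0.414 with an estimated correlation). Hao2 fell (at least 9.78-fold) and Cyp17a1 rose (2.66). In the interferon-induced list 1 of 20 measured genes rose and 12 fell (2 and 14 adjusted over the list alone). The interferon list median was -0.44, with a camera adjusted p of 8.34e-05 (adjusted p = 0.531 with an estimated correlation). In the circadian clock list 3 of 17 measured genes rose and 8 fell (3 and 9 adjusted over the list alone). The clock median was -0.45, with a camera adjusted p of 0.00635 (adjusted p = 0.414 with an estimated correlation). In the oxidative phosphorylation list 1 of 23 measured genes rose and 10 fell (1 and 11 adjusted over the list alone). The oxidative phosphorylation median was -0.29, with a camera adjusted p of 4.36e-04 (adjusted p = 0.629 with an estimated correlation). In the macrophage and Kupffer cell list 8 of 15 measured genes rose and 1 fell (8 and 2 adjusted over the list alone). The macrophage median was 0.46, with a camera adjusted p of 0.0158 (adjusted p = 0.638 with an estimated correlation). Marco, a scavenger receptor, rose by 2.72 ± 0.16. In the stellate cell and fibroblast list 0 of 12 measured genes rose and 4 fell (0 and 4 adjusted over the list alone). The stellate cell median was -0.20, with a camera adjusted p of 0.0189 (adjusted p = 0.382 with an estimated correlation). Lrat, which esterifies retinol, fell by 2.28. In the pericentral hepatocyte list 1 of 11 measured genes rose and 8 fell (1 and 9 adjusted over the list alone). The pericentral median was -0.63, with a camera adjusted p of 2.49e-05 (adjusted p = 0.382 with an estimated correlation). In the periportal list 2 of 8 measured genes rose and 5 fell (2 and 6 adjusted over the list alone). The periportal median was -1.05, with a camera adjusted p of 0.00388 (adjusted p = 0.531 with an estimated correlation). Cyp1a2, Glul and the urea cycle gene Cps1 changed by -2.07, -1.71 and -1.99.

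Another 12 lists were not called in wild type: triglyceride synthesis and lipid droplets (camera adjusted p = 0.823), gluconeogenesis (0.357), male-biased genes (0.823), acute phase proteins (0.49), immediate early and heat shock genes (0.357), lymphocytes (0.556), neutrophils (0.097), red blood cell precursors (0.268), endothelial cells (0.0655), bile duct cells (0.405), adipocytes (0.555) and pancreatic acinar cells (0.556). For triglyceride synthesis and for male-biased genes the median and the mean differed in sign.

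By limma with Benjamini-Hochberg adjustment, 5921 of 19119 probe sets were called in wild type, 2827 up and 3094 down, of which 498 and 630 changed at least 2-fold. The median standard error was 0.121. At the authors' threshold in a Cyber-T-style test the count was 1129.

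**Figure D2:**
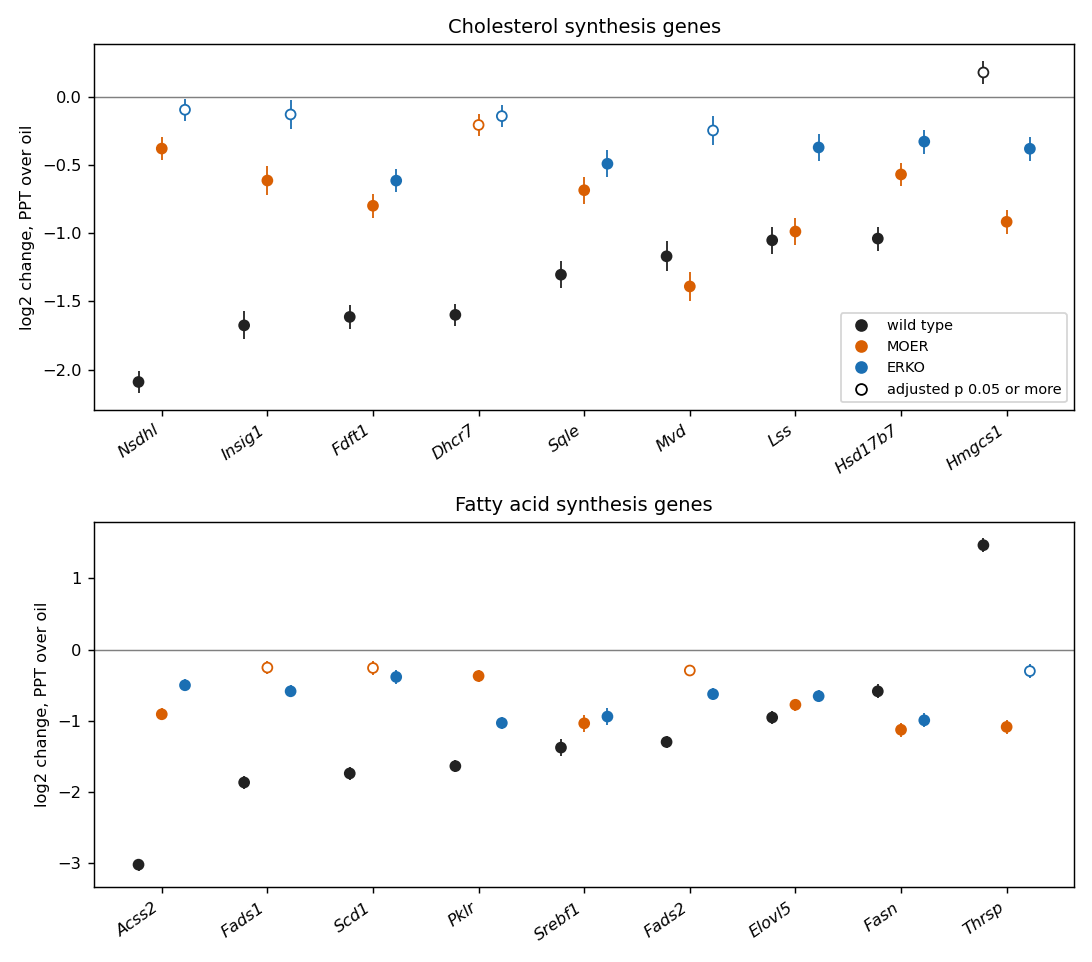
Log2 change with PPT (points, with bars of 1 standard error) of cholesterol synthesis genes (upper panel) and fatty acid synthesis genes (lower panel) in wild type, MOER and ERKO livers, 2 arrays per group, with open points for genes that did not pass the test. Srebf1 changed by -1.38, -1.04 and -0.94 in wild type, MOER and ERKO, and Thrsp by 1.47, -1.09 and -0.30.

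The second comparison asked what PPT changes in the mice that the labels give as having the receptor at the membrane alone. In MOER livers Srebf1 fell from 528 ± 8.96 to 249.9 ± 27.3 (n = 2), a log2 change of -1.04 (adjusted p = 4.03e-04), and Fasn from 518 ± 23.4 to 229 ± 9.31, -1.13 (adjusted p = 6.08e-05). Mvd, Lss and Hmgcs1, enzymes of the mevalonate and sterol pathway, changed by -1.39 ± 0.11, -0.99 ± 0.100 and -0.92 ± 0.087. Cyp7a1 fell from 3205 ± 116 to 1387 ± 72.7 and Cyp8b1 from 538 ± 46 to 264 ± 12. Acaca changed by -0.38 (adjusted p = 0.0454) and lost its call in 10 leave-one-out fits, and Scd1 gave -0.26 without passing (adjusted p = 0.207).

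In the cholesterol synthesis list 0 of 20 measured genes rose and 14 fell (0 and 17 adjusted over the list alone). The cholesterol synthesis median was -0.59, with a camera adjusted p of 2.51e-22 (adjusted p = 0.0932 with an estimated correlation). In the fatty acid synthesis list 0 of 18 measured genes rose and 11 fell (0 and 15 adjusted over the list alone). The fatty acid synthesis median was -0.45, with a camera adjusted p of 2.02e-19 (adjusted p = 0.0789 with an estimated correlation). With a 2-fold minimum, 1 of the 20 cholesterol synthesis genes and 3 of the 18 fatty acid synthesis genes fell in MOER, against 15 and 9 in wild type. Thrsp changed by -1.09 ± 0.097, Acss2 by -0.91 ± 0.086 and Acly by -0.73 ± 0.093. The 16 secreted hepatocyte genes had a median of 0.00196 with 0 called. In the bile acid and sterol disposal list 0 of 17 measured genes rose and 5 fell (1 and 6 adjusted over the list alone). The bile acid median was -0.10, with a camera adjusted p of 2.07e-05 (adjusted p = 0.368 with an estimated correlation). In the fatty acid oxidation list 2 of 23 measured genes rose and 6 fell (4 and 9 adjusted over the list alone). The oxidation median was -0.01, with a camera adjusted p of 0.00269 (adjusted p = 0.567 with an estimated correlation). In the drug metabolism list 0 of 11 measured genes rose and 5 fell (0 and 8 adjusted over the list alone). The drug metabolism median was -0.40, with a camera adjusted p of 1.26e-07 (adjusted p = 0.235 with an estimated correlation). In the gluconeogenesis list 5 of 12 measured genes rose and 0 fell (5 and 0 adjusted over the list alone). The gluconeogenesis median was 0.28, with a camera adjusted p of 4.64e-05 (adjusted p = 0.258 with an estimated correlation). Pck1, the gene of phosphoenolpyruvate carboxykinase, rose by 1.35 ± 0.10. Cyp17a1 rose from 219 ± 4.6 to 2501 ± 72.2 and the oestrogen sulfotransferase gene Sult1e1 from 122 ± 16.4 to 1213 ± 174. Cish and Socs2, targets of growth hormone signalling, fell at least 1.23-fold and by a log2 change of 1.51, and Igf1 gave -0.32 (adjusted p = 0.0671).

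Inflammatory genes rose in MOER. In the acute phase list 18 of 25 measured genes rose and 0 fell (19 and 0 adjusted over the list alone). The acute phase median was 0.82, with a camera adjusted p of 2.63e-32 (adjusted p = 0.0932 with an estimated correlation). Lcn2 rose from 2327 ± 52.8 to 9857 ± 108 and the chemokine gene Cxcl1 from 299.8 ± 35 to 1883 ± 26.1. In the interferon-induced list 8 of 20 measured genes rose and 0 fell (12 and 0 adjusted over the list alone). The interferon list median was 0.35, with a camera adjusted p of 2.43e-13 (adjusted p = 0.235 with an estimated correlation). Irf7 rose by 1.08 ± 0.13. In the macrophage and Kupffer cell list 5 of 15 measured genes rose and 1 fell (8 and 2 adjusted over the list alone). The macrophage median was 0.34, with a camera adjusted p of 1.11e-05 (adjusted p = 0.368 with an estimated correlation). Marco rose by 2.22 ± 0.16. In the male-biased list 2 of 18 measured genes rose and 7 fell (3 and 7 adjusted over the list alone). The male-biased median was -0.12, with a camera adjusted p of 0.0109 (adjusted p = 0.567 with an estimated correlation). In the female-biased list 2 of 19 measured genes rose and 10 fell (2 and 11 adjusted over the list alone). The female-biased median was -0.54, with a camera adjusted p of 6.9e-07 (adjusted p = 0.236 with an estimated correlation). In the circadian clock list 4 of 17 measured genes rose and 2 fell (4 and 3 adjusted over the list alone). The clock median was 0.22, with a camera adjusted p of 0.0127 (adjusted p = 0.368 with an estimated correlation). Arntl changed by -0.78 and Dbp by 1.02. In the oxidative phosphorylation list 0 of 23 measured genes rose and 0 fell (0 and 0 adjusted over the list alone). The oxidative phosphorylation median was -0.11, with a camera adjusted p of 0.0101 (adjusted p = 0.662 with an estimated correlation). In the stellate cell list 1 of 12 measured genes rose and 0 fell (1 and 0 adjusted over the list alone). The stellate cell median was 0.20, with a camera adjusted p of 0.0207 (adjusted p = 0.277 with an estimated correlation). In the bile duct list 1 of 5 measured genes rose and 0 fell (2 and 0 adjusted over the list alone). The bile duct median was 0.28, with a camera adjusted p of 0.0301 (adjusted p = 0.235 with an estimated correlation).

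Pancreatic genes fell in MOER. In the acinar cell list 0 of 10 measured genes rose and 9 fell (0 and 10 adjusted over the list alone). The acinar median was -3.17, with a camera adjusted p of 9.84e-29 (adjusted p = 0.00555 with an estimated correlation). Cpb1, a pancreatic carboxypeptidase, fell from 12634 ± 815 to 15.9 ± 4.78 (at least 209-fold), Try4, a trypsin, from 20948 ± 5972 to 80.4 ± 8.67, and Rnase1 from 2916 ± 94.6 to 41 ± 0.721 (at least 48.2-fold). The MOER oil arrays stood apart: 7 of the 10 acinar genes were more than 2-fold above every other group there, and 2 of the 10 passed the brightness filter in both wild type oil arrays.

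The remaining 12 lists were not called in MOER: triglyceride synthesis (camera adjusted p = 0.744), oestrogen-responsive genes (0.264), the unfolded protein response (0.744), cell cycle (0.54), immediate early genes (0.693), lymphocytes (0.229), neutrophils (0.252), red blood cell precursors (0.269), endothelial cells (0.751), adipocytes (0.693), pericentral hepatocytes (0.744) and periportal hepatocytes (0.628). In the triglyceride, cell cycle, red blood cell, endothelial and adipocyte lists the median and the mean differed in sign.

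In MOER 890 probe sets were called, 449 up and 441 down, of which 77 and 92 changed at least 2-fold. The count was 1470 after quantile normalisation. It ranged from 437 without MOER PPT replicate 1 to 1672 without either ERKO oil array, and 6 of the 12 arrays moved it by more than 1.5 times.

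The third comparison asked what PPT changes in the mice that the labels give as lacking the receptor. Fatty acid synthesis genes fell in ERKO as well: Srebf1 from 454 ± 68.3 to 228 ± 23.4 (n = 2), -0.94 (adjusted p = 5.54e-04), and Fasn from 604 ± 65.7 to 295 ± 11.6, -0.99 (adjusted p = 1.01e-04). In that list 0 of 18 measured genes rose and 11 fell (0 and 14 adjusted over the list alone). The fatty acid synthesis median was -0.42, with a camera adjusted p of 1.3e-08 (adjusted p = 0.26 with an estimated correlation). Pklr changed by -1.03 ± 0.090 and Acaca by -0.46 ± 0.093. In the cholesterol synthesis list 0 of 20 measured genes rose and 7 fell (0 and 7 adjusted over the list alone). The cholesterol synthesis median was -0.21, with a camera adjusted p of 1.45e-04 (adjusted p = 0.331 with an estimated correlation). The 7 became 4 without ERKO oil replicate 1, 12 without ERKO oil replicate 2, 2 without ERKO PPT replicate 1, 1 without ERKO PPT replicate 2, 4 without either wild type PPT array and 3 without the filter. With a 2-fold minimum 0 cholesterol synthesis genes and 1 fatty acid synthesis gene fell in ERKO. The cholesterol synthesis median lay between -0.093 and -0.31 over these alternatives. Fdft1 changed by -0.61 ± 0.087 and Sqle by -0.49 ± 0.100. Cyp7a1 fell from 4049 ± 181 to 1885 ± 27.8, while Cyp8b1 gave 0.31 (adjusted p = 0.0608). The 16 secreted hepatocyte genes had a median of -0.05, with 5 called, and clock genes shifted in these arrays, as given next.

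Clock and sex-biased genes changed with PPT in ERKO. In the circadian clock list 3 of 17 measured genes rose and 12 fell (3 and 13 adjusted over the list alone). The clock median was -0.48, with a camera adjusted p of 7.38e-06 (adjusted p = 0.26 with an estimated correlation). Arntl rose from 69.1 ± 0.516 to 211 ± 8.54 and Dbp, which peaks at the opposite time of day, fell from 576 ± 62.2 to 202 ± 0.523. In the male-biased list 11 of 18 measured genes rose and 1 fell (12 and 1 adjusted over the list alone). The male-biased median was 0.62, with a camera adjusted p of 2.71e-09 (adjusted p = 0.26 with an estimated correlation). Cyp4a12a rose from 503 ± 32 to 4652 ± 89 and Elovl3 from 163 ± 60.4 to 1643 ± 65.8. In the female-biased list 0 of 19 measured genes rose and 16 fell (0 and 18 adjusted over the list alone). The female-biased median was -1.16, with a camera adjusted p of 1.79e-22 (adjusted p = 0.142 with an estimated correlation). A1bg fell from 1882 ± 148 to 57.5 ± 8.87 and Cyp2b13 from 1078 ± 116 to 106 ± 0.0778.

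Other metabolic and immune lists were called in ERKO. In the triglyceride synthesis list 0 of 19 measured genes rose and 10 fell (1 and 11 adjusted over the list alone). The triglyceride median was -0.29, with a camera adjusted p of 8.45e-06 (adjusted p = 0.26 with an estimated correlation). In the fatty acid oxidation list 1 of 23 measured genes rose and 15 fell (1 and 18 adjusted over the list alone). The oxidation median was -0.44, with a camera adjusted p of 3.59e-09 (adjusted p = 0.26 with an estimated correlation). In the bile acid list 2 of 17 measured genes rose and 11 fell (3 and 11 adjusted over the list alone). The bile acid median was -0.54, with a camera adjusted p of 2.97e-06 (adjusted p = 0.26 with an estimated correlation). In the gluconeogenesis list 1 of 12 measured genes rose and 7 fell (1 and 7 adjusted over the list alone). The gluconeogenesis median was -0.38, with a camera adjusted p of 9.64e-04 (adjusted p = 0.26 with an estimated correlation). In the drug metabolism list 1 of 11 measured genes rose and 7 fell (1 and 7 adjusted over the list alone). The drug metabolism median was -0.46, with a camera adjusted p of 1.16e-04 (adjusted p = 0.26 with an estimated correlation). In the periportal list 0 of 8 measured genes rose and 6 fell (0 and 7 adjusted over the list alone). The periportal median was -0.58, with a camera adjusted p of 7.91e-07 (adjusted p = 0.26 with an estimated correlation). In the pericentral list 1 of 11 measured genes rose and 3 fell (1 and 5 adjusted over the list alone). The pericentral median was -0.19, with a camera adjusted p of 0.0206 (adjusted p = 0.41 with an estimated correlation). In the oestrogen-responsive list 1 of 15 measured genes rose and 4 fell (1 and 5 adjusted over the list alone). The oestrogen list median was -0.04, with a camera adjusted p of 0.0386 (adjusted p = 0.379 with an estimated correlation). In the interferon-induced list 0 of 20 measured genes rose and 4 fell (0 and 6 adjusted over the list alone). The interferon list median was -0.26, with a camera adjusted p of 0.00304 (adjusted p = 0.449 with an estimated correlation). In the macrophage list 0 of 15 measured genes rose and 6 fell (0 and 6 adjusted over the list alone). The macrophage median was -0.28, with a camera adjusted p of 7.71e-04 (adjusted p = 0.403 with an estimated correlation). In the neutrophil list 0 of 9 measured genes rose and 5 fell (0 and 6 adjusted over the list alone). The neutrophil median was -0.54, with a camera adjusted p of 0.00399 (adjusted p = 0.301 with an estimated correlation). In the acute phase list 6 of 25 measured genes rose and 3 fell (9 and 3 adjusted over the list alone). The acute phase median was 0.23, with a camera adjusted p of 0.0459 (adjusted p = 0.649 with an estimated correlation). Saa3 rose from 743 ± 42.5 to 11227 ± 516.

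Transcripts typical of other tissues rose in ERKO. Smpx and Tnnc2, of striated muscle, rose from 28.1 ± 5.01 to 6351 ± 479 (at least 113-fold) and from 68.1 ± 4.43 to 5999 ± 708. Krtdap and Rptn, of cornified epithelium, rose at least 52.1-fold and 59.8-fold, the serpin gene Serpinb3a at least 115-fold, and Scgb1a1, of airway club cells, from 5.12 ± 2.28 to 1148 ± 19.9. In the stellate cell and fibroblast list, where Des and Acta2 are also muscle genes, 6 of 12 measured genes rose and 0 fell (6 and 1 adjusted over the list alone). The stellate cell median was 0.28, with a camera adjusted p of 0.0103 (adjusted p = 0.26 with an estimated correlation). Des rose at least 3.68-fold and Acta2 by 1.10 ± 0.15. Of 20 skeletal muscle markers, 11 were more than 2-fold above every other group in ERKO PPT, as were 2 of 17 markers of stratified epithelium and 0 of 14 of lung epithelium. Of these markers 5, 8 and 7 passed the brightness filter in both wild type oil arrays.

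The other 10 lists were not called in ERKO: the unfolded protein response (camera adjusted p = 0.234), cell cycle (0.057), immediate early genes (0.413), oxidative phosphorylation (0.461), lymphocytes (0.0938), red blood cell precursors (0.536), endothelial cells (0.165), bile duct cells (0.0714), adipocytes (0.0771) and acinar cells (0.138). In all, 3430 probe sets were called in ERKO, 1812 up and 1618 down, of which 226 and 81 changed at least 2-fold. The balance turned with the scaling: median centring gave 1334 up and 1964 down, quantile normalisation 2018 up and 2690 down, and leaving out ERKO oil replicate 2 gave 1919 up and 3114 down. The count was 576 when the 4 ERKO arrays were fitted alone. It ranged from 1200 without ERKO PPT replicate 2 to 5346 without ERKO oil replicate 1, and 3 of the 12 arrays moved it by more than 1.5 times.

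**Figure D3:**
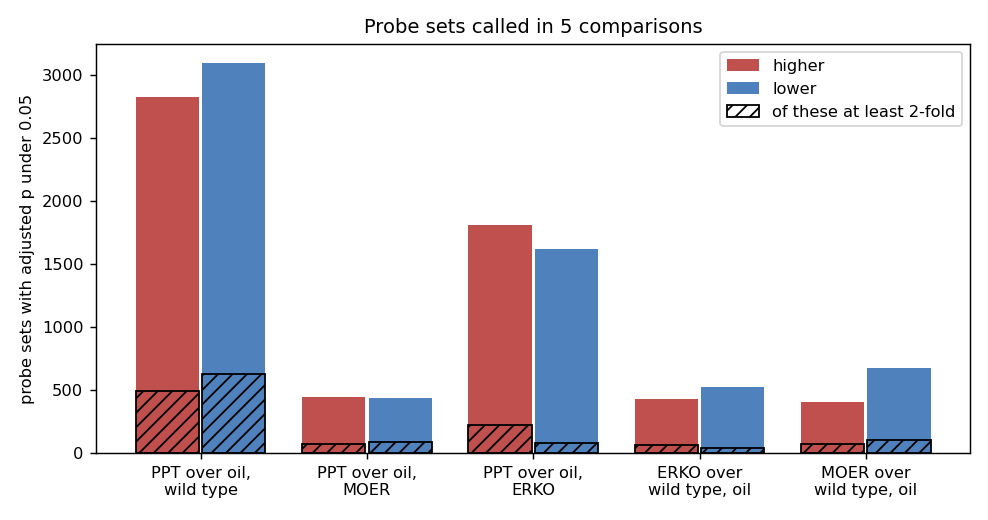
Number of probe sets called higher (red) or lower (blue) at an adjusted p under 0.05 in the 3 PPT responses and the 2 comparisons of mutants with wild type under oil, with the part that changed at least 2-fold hatched. The wild type response had 5921 calls, the MOER response 890 and the ERKO response 3430.

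The responses of 2 genotypes were then compared by the difference of their log2 changes. Against ERKO, the wild type response was lower for Cyp7a1 and Cyp8b1, whose dim wild type PPT arrays leave the size open, and for Acss2 (difference -2.52 ± 0.12), Nsdhl (-2.00 ± 0.12) and Scd1 (-1.36 ± 0.13), with adjusted p of 6.16e-09, 1.87e-08, 2.01e-07, 8.49e-07 and 4.41e-05. It was not shown to differ for Srebf1 (-0.44, adjusted p = 0.093), Fasn (0.41, adjusted p = 0.0622) or Acaca (-0.12, adjusted p = 0.57). The cholesterol synthesis list differed (median -0.96, camera adjusted p = 7.02e-11, adjusted p = 0.348 with an estimated correlation), as did the fatty acid synthesis list (median -0.49, camera adjusted p = 0.00178, adjusted p = 0.49 with an estimated correlation) and the unfolded protein response list (median 1.43, camera adjusted p = 8.54e-13, adjusted p = 0.103 with an estimated correlation). In all 16 of 28 lists differed between wild type and ERKO, 0 of them with the estimated correlation. The wild type response was also higher for cell cycle (median 0.52, camera adjusted p = 5.52e-05), macrophages and Kupffer cells (0.60, 1.06e-04), neutrophils (1.02, 0.00198), female-biased genes (0.38, 0.00278), oestrogen-responsive genes (0.25, 0.0254) and triglyceride synthesis (0.23, 0.0254). It was also lower for stellate cells and fibroblasts (median -0.63, camera adjusted p = 1.62e-04), pericentral hepatocytes (-0.55, 0.00158), male-biased genes (-0.46, 0.00194), bile acid and sterol disposal (-0.51, 0.00555), drug metabolism (-0.46, 0.0135), endothelial cells (-0.14, 0.0254) and oxidative phosphorylation (-0.25, 0.0373).

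Against ERKO, the MOER response was lower for Mvd (-1.14 ± 0.15, adjusted p = 0.00104), Lss (-0.62 ± 0.14, adjusted p = 0.019), Hmgcs1 (-0.54 ± 0.12, adjusted p = 0.0194), Thrsp (-0.78 ± 0.14, adjusted p = 0.00515) and Cyp8b1 (-1.29 ± 0.15, adjusted p = 2.77e-04). It was not shown to differ for Srebf1 (-0.10, adjusted p = 0.776), Fasn (-0.13, adjusted p = 0.604), Acaca (0.08, adjusted p = 0.751), Scd1 (0.13, adjusted p = 0.607), Acss2 (-0.41, adjusted p = 0.0556) or Cyp7a1 (-0.10, adjusted p = 0.653). The cholesterol synthesis list differed (median -0.31, camera adjusted p = 8.33e-05, adjusted p = 0.441 with an estimated correlation), and the fatty acid synthesis list did not pass (median -0.13, camera adjusted p = 0.34). Acute phase proteins (median 0.62, camera adjusted p = 3.13e-09, adjusted p = 0.349 with an estimated correlation) and interferon-induced genes (median 0.70, camera adjusted p = 1.22e-09, adjusted p = 0.282 with an estimated correlation) had a higher response in MOER than in ERKO. So had macrophage and Kupffer cell markers (median 0.59, camera adjusted p = 2.13e-06, adjusted p = 0.37 with an estimated correlation), female-biased genes (median 1.55, camera adjusted p = 2.76e-14, adjusted p = 0.206 with an estimated correlation) and clock genes (median 0.70, camera adjusted p = 1.76e-06, adjusted p = 0.282 with an estimated correlation), with all 10 of the Dbp phase called higher, while male-biased genes had a lower response (median -0.43, camera adjusted p = 8.61e-08, adjusted p = 0.282 with an estimated correlation). The cholesterol synthesis list was thus 1 of 13 lists, of 28, that differed between MOER and ERKO. The response was also higher in MOER for periportal hepatocytes (median 0.48, camera adjusted p = 2.87e-06), gluconeogenesis (0.51, 5.6e-06), triglyceride synthesis (0.23, 0.00348) and fatty acid oxidation (0.36, 0.0287) and lower for adipocytes (median -0.20, camera adjusted p = 0.0367). The acinar list had a lower response too (median -3.25, camera adjusted p = 8.02e-17, adjusted p = 0.0234 with an estimated correlation) and alone was called with the estimated correlation. The acinar genes were high in the MOER oil arrays.

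Between wild type and MOER, the response of Cyp7a1 was lower in wild type by a size its dim wild type PPT arrays leave open (adjusted p = 5.26e-09). The response of Scd1 differed by -1.48 ± 0.13, of Hmgcs1 by 1.10 ± 0.12 and of Thrsp by 2.55 ± 0.14, with adjusted p of 2.29e-05, 9.93e-05 and 6.32e-07. Srebf1 (-0.34, adjusted p = 0.205), Mvd (0.22, adjusted p = 0.389) and Lss (-0.06, adjusted p = 0.824) were not shown to differ. The cholesterol synthesis list did differ, with a lower response in wild type (median -0.60, camera adjusted p = 2.31e-06, adjusted p = 0.445 with an estimated correlation), 14 genes lower and 1 higher of 20, as did the fatty acid synthesis list (median -0.34, camera adjusted p = 0.00759, adjusted p = 0.445 with an estimated correlation), 8 lower and 2 higher of 18. The cell cycle list had a higher response in wild type (median 0.65, camera adjusted p = 2.31e-06, adjusted p = 0.0373 with an estimated correlation), as had the unfolded protein response list (median 1.17, camera adjusted p = 1.34e-11, adjusted p = 0.0906 with an estimated correlation). The interferon-induced list (median -0.76, camera adjusted p = 2.56e-10, adjusted p = 0.445 with an estimated correlation) and the acute phase list (median -0.64, camera adjusted p = 5.64e-06, adjusted p = 0.445 with an estimated correlation) had a lower one. In all 16 of 28 lists differed between wild type and MOER, 2 of them (acinar cells and cell cycle) with the estimated correlation. The wild type response was also higher for acinar cells (median 3.39, camera adjusted p = 1.13e-11) and neutrophils (0.73, adjusted p = 0.0315). It was also lower for periportal hepatocytes (median -0.69, camera adjusted p = 6.14e-05), pericentral hepatocytes (-0.80, 1.03e-04), bile acid and sterol disposal (-0.89, 3.30e-04), stellate cells and fibroblasts (-0.49, 9.10e-04), female-biased genes (-0.65, 0.00166), drug metabolism (-0.23, 0.0029), gluconeogenesis (-0.55, 0.00547) and circadian clock (-0.37, 0.00686).

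The 3 differences called 4266 probe sets for wild type minus ERKO (1975 up, 2291 down), 2193 for MOER minus ERKO (1125 up, 1068 down) and 4124 for wild type minus MOER (2007 up, 2117 down). The first was 6735 without ERKO oil replicate 1. The second was 3500 after quantile normalisation, 1037 with the compared arrays alone, and between 1078 without ERKO PPT replicate 2 and 4802 without ERKO oil replicate 1, with 8 of 12 arrays moving it by more than 1.5 times.

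The comparison the study states is of genes that PPT changed in wild type and MOER but not in ERKO. Prtn3 rose in wild type (5.57) and MOER (2.02) and gave -0.24 in ERKO, and Nrep gave -3.04, -2.41 and 0.20. Cyp8b1 gave -4.24, -0.98 and 0.31, the thioesterase gene Acot1 -2.34, -1.71 and -0.52, and Onecut1, a hepatic transcription factor, -2.14, -1.34 and -0.25. For these 3 the wild type value, and for Acot1 the MOER value also, depends on the 16 added to each intensity, since the PPT arrays were dim, and so does the mean response of Cyp8b1. Sult1e1 gave 0.82, 3.16 and -0.26 (dim in ERKO PPT), the chemokine gene Cxcl13 1.27, 2.21 and 0.17, and Gm4952 -2.98, -0.47 and -0.02. Srebf1, Fasn and Acaca were called in all 3 genotypes and so are not in this set. The mean response of wild type and MOER minus that of ERKO was 4.03 (adjusted p = 1.47e-06) for Prtn3, -2.93 (2.63e-07) for Nrep, -2.92 (1.18e-07) for Cyp8b1 and -0.27 (0.257) for Srebf1. Prtn3, Nrep and Cyp8b1 were picked on the same arrays, which favours small p-values. The cholesterol synthesis list had a lower mean response (median -0.67, camera adjusted p = 2.4e-10, 0.237 with an estimated correlation), as had the fatty acid synthesis list (-0.24, 0.00356 and 0.402). These were 2 of 18 lists of 28 that differed for that mean, 0 of them with the estimated correlation. The mean response was also lower for acinar cells (median -2.08, camera adjusted p = 6.44e-10), male-biased genes (-0.54, 2.13e-06), stellate cells and fibroblasts (-0.45, 0.0016), endothelial cells (-0.23, 0.0199) and adipocytes (-0.54, 0.0381). It was higher for female-biased genes (median 0.96, camera adjusted p = 1.81e-09), the unfolded protein response (0.61, 3.49e-09), macrophages and Kupffer cells (0.46, 1.67e-06), circadian clock (0.38, 0.00137), triglyceride synthesis (0.22, 0.00177), neutrophils (0.84, 0.00272), gluconeogenesis (0.32, 0.00342), acute phase proteins (0.17, 0.00356), cell cycle (0.20, 0.0141), oestrogen-responsive genes (0.17, 0.034) and interferon-induced genes (0.10, 0.0486). Acot1 in ERKO passed the test with quantile normalisation (-0.56), median centring (-0.57), the replicate block and the trended fit, both at -0.52, and without ERKO oil replicate 2 (-0.82), and Cyp8b1 in ERKO with quantile normalisation (0.28) and without ERKO oil replicate 1 (0.43). Gm4952 in MOER lost its call without MOER oil replicate 1 (-0.49), MOER oil replicate 2 (-0.45) or MOER PPT replicate 1 (-0.41).

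Of the probe sets called in both wild type and MOER, 371 moved in 1 direction (145 up, 226 down, for 293 genes) and 276 in opposite directions, where independent calls would give 66.4 up and 71.4 down in both. Opposite calls exceeded independence as well: 109 rose in wild type and fell in MOER (65.2 if independent), and 167 fell and rose (72.7 if independent). Of the 371, 168 were not called in ERKO (70 up, 98 down, 136 genes), 150 were called there with the same sign and 53 with the opposite sign. A test of the mean wild type and MOER response against ERKO passed for 143 of the 168 (59 up, 84 down, 118 genes) and not for 25. Wild type and ERKO shared 1255 calls of 1 sign against 458 of opposite sign, and MOER and ERKO 206 against 184. The correlation of log2 changes across probe sets was 0.10 for wild type and MOER, 0.17 for wild type and ERKO, and 0.045 for MOER and ERKO. That contrast of the mean called 3064 probe sets, 1431 up and 1633 down. The 168 became 85 without MOER PPT replicate 1 and 316 without ERKO oil replicate 1, and 38 with a 2-fold minimum.

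Genotypes were also compared under oil. In ERKO, Sult2a3, a sulfotransferase, was at 173 ± 10.1 against 47188 ± 5788 in wild type (n = 2), and Pctp, a phosphatidylcholine transfer protein, at 268 ± 23.2 against 1229 ± 6.2. Cyp4a12a, of male liver, was at 503 ± 32 against 22 ± 11.5. The neutrophil genes S100a8 and S100a9 were higher, S100a8 at least 13.4-fold and S100a9 by 3.13 ± 0.16, Lcn2 by 2.63 ± 0.089 and the amyloid gene Saa1 by 2.20 ± 0.13. In the neutrophil list 6 of 9 measured genes were higher and 0 lower (7 and 0 adjusted over the list alone). The neutrophil median was 1.13 (camera adjusted p = 4.33e-12, adjusted p = 0.28 with an estimated correlation). In the acute phase list 9 of 25 measured genes were higher and 0 lower (13 and 0 adjusted over the list alone). The acute phase median was 0.28 (camera adjusted p = 4.92e-12, adjusted p = 0.578 with an estimated correlation). In the male-biased list 6 of 18 measured genes were higher and 0 lower (7 and 2 adjusted over the list alone). The male-biased median was 0.10 (camera adjusted p = 2.43e-05, adjusted p = 0.632 with an estimated correlation). In the unfolded protein response list 7 of 15 measured genes were higher and 0 lower (8 and 1 adjusted over the list alone). The stress response median was 0.24 (camera adjusted p = 2.43e-05, adjusted p = 0.471 with an estimated correlation). In the cholesterol synthesis list 2 of 20 measured genes were higher and 0 lower (3 and 1 adjusted over the list alone). The cholesterol synthesis median was 0.18 (camera adjusted p = 1.21e-04, adjusted p = 0.651 with an estimated correlation). In the endothelial list 0 of 12 measured genes were higher and 4 lower (0 and 9 adjusted over the list alone). The endothelial median was -0.39 (camera adjusted p = 4.97e-05, adjusted p = 0.651 with an estimated correlation). Of the 10 lists called in ERKO under oil, the other 4 were higher for lymphocytes (median 0.17, camera adjusted p = 0.00778) and bile acid and sterol disposal (0.10, 0.0436) and lower for fatty acid oxidation (median -0.20, camera adjusted p = 0.00153) and oestrogen-responsive genes (-0.16, 0.00778). The fatty acid synthesis list was not called (median -0.03, camera adjusted p = 0.51, mean of opposite sign), and Srebf1 differed by 0.13 (adjusted p = 0.534).

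In MOER under oil, Sult2a3 was at 259.5 ± 34.6, Cyp17a1 at 219 ± 4.6 against 1590.2 ± 3.41 in wild type, and Cyp4a12a at 1374 ± 85.8. H2-Ea, a class II histocompatibility gene that the b haplotype does not express, was at 5613 ± 11.9 against 17.6 ± 3.12, at least 104-fold. In the acinar cell list 10 of 10 measured genes were higher and 0 lower (10 and 0 adjusted over the list alone). The acinar median was 3.58 (camera adjusted p = 3.66e-25, adjusted p = 0.00781 with an estimated correlation). Cpb1 was higher at least 234-fold. In the neutrophil list 6 of 9 measured genes were higher and 0 lower (7 and 0 adjusted over the list alone). The neutrophil median was 0.77 (camera adjusted p = 1.3e-07, adjusted p = 0.399 with an estimated correlation). In the male-biased list 8 of 18 measured genes were higher and 1 lower (10 and 1 adjusted over the list alone). The male-biased median was 0.42 (camera adjusted p = 1.3e-07, adjusted p = 0.473 with an estimated correlation). In the female-biased list 2 of 19 measured genes were higher and 9 lower (4 and 11 adjusted over the list alone). The female-biased median was -0.46 (camera adjusted p = 2.17e-04, adjusted p = 0.473 with an estimated correlation). In the acute phase list 6 of 25 measured genes were higher and 1 lower (9 and 1 adjusted over the list alone). The acute phase median was 0.23 (camera adjusted p = 6.57e-06, adjusted p = 0.538 with an estimated correlation). In the cholesterol synthesis list 2 of 20 measured genes were higher and 0 lower (5 and 0 adjusted over the list alone). The cholesterol synthesis median was 0.21 (camera adjusted p = 2.96e-04, adjusted p = 0.538 with an estimated correlation). In the clock list 0 of 17 measured genes were higher and 5 lower (1 and 9 adjusted over the list alone). The clock median was -0.39 (camera adjusted p = 8.10e-04, adjusted p = 0.473 with an estimated correlation). Of the 12 lists called in MOER under oil, the other 5 were higher for the unfolded protein response (median 0.25, camera adjusted p = 8.34e-04) and lower for fatty acid oxidation (median -0.20, camera adjusted p = 1.68e-04), interferon-induced genes (-0.33, 2.17e-04), gluconeogenesis (-0.35, 8.34e-04) and oestrogen-responsive genes (-0.18, 0.0453). The fatty acid synthesis list was not called (median 0.11, camera adjusted p = 0.256), and Srebf1 differed by 0.35 (adjusted p = 0.114). Genetic background was not tested, and these contrasts do not separate it from the receptor.

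By limma 957 probe sets were called in ERKO against wild type under oil (428 up, 529 down), 1082 in MOER against wild type (407 up, 675 down) and 392 in MOER against ERKO (171 up, 221 down). In the last comparison acinar genes were higher (median 3.43, camera adjusted p = 1.53e-31, adjusted p = 0.00414 with an estimated correlation) and clock genes lower (median -0.48, camera adjusted p = 1.52e-07, adjusted p = 0.267 with an estimated correlation) in MOER. Of the 10 lists called there, the other 8 were higher for pericentral hepatocytes (median 0.22, camera adjusted p = 0.00122) and endothelial cells (0.21, 0.00486) and lower for neutrophils (median -0.60, camera adjusted p = 5.35e-05), interferon-induced genes (-0.13, 1.48e-04), acute phase proteins (-0.14, 4.78e-04), female-biased genes (-0.11, 7.71e-04), triglyceride synthesis (-0.10, 0.00124) and lymphocytes (-0.16, 0.0151). The 3 counts ranged over 230 to 6329, 249 to 3332 and 123 to 2151 as 1 array was left out, highest without ERKO oil replicate 1 (for the second, without either ERKO oil array) and lowest without wild type oil replicate 2 for the first and MOER oil replicate 2 for the others, with 11, 6 and 8 of the 12 arrays moving them by more than 1.5 times. They were 1673, 1523 and 813 after quantile normalisation, and median centring gave 1716 for the second.

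The mutants shared 380 calls of 1 sign against the same wild type oil arrays (171 up, 209 down), with 3 of opposite sign. Independent calls would give 9.11 up and 18.7 down. Their differences from wild type correlated at 0.593 across probe sets, where the shared control alone gave 0.499 in 20 simulated draws, with 0 probe sets called in both. The draws held no genotype difference, so hardly any call could arise. The 0 does not show how many of the 380 calls the shared control adds. The covariance was 0.0588 against 0.00979 simulated, a difference of 0.049. The draws took arrays as independent, without the link between equally numbered oil arrays (0.276 for wild type with ERKO, 0.354 for wild type with MOER, 0.377 for ERKO with MOER). In a split chosen after seeing the data, with wild type oil replicate 1 as the control of ERKO and replicate 2 as that of MOER the covariance was 0.0526, and 0.0491 with the 2 exchanged. Each such control is 1 array, and part of the excess may come from the shared controls.

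**Figure D4:**
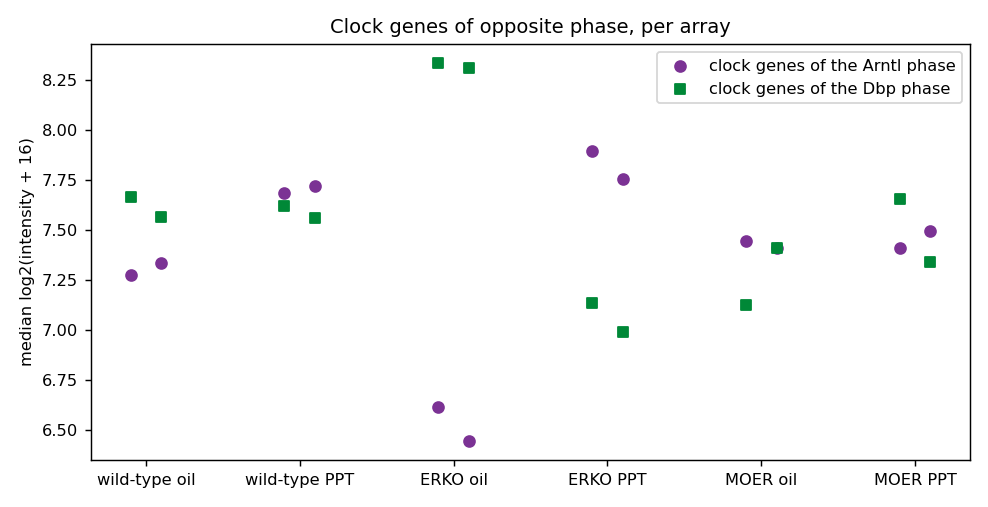
Median log2(intensity + 16) of 4 clock genes of the Arntl phase (circles) and 10 of the Dbp phase (squares) on each of the 12 arrays. The median over genes of the log2 change with PPT, first list minus second, was 0.53 in wild type, -0.68 in MOER and 1.69 in ERKO. These are medians of the changes of single genes, and they differ from the changes of the plotted medians.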

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

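The acinar excess, the muscle list alone and the comparison between arrays of a group are tests chosen only after the result was seen, while the joint test of muscle and stratified epithelium was written before its result. Each result in this part was picked out because the PPT response differed between 2 genotypes by a test of that difference.

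Wild type and ERKO responses differed for 4266 probe sets. The genes the rule names were Serpinb3a (-7.59), Serpinb12 (-7.46) and Smpx (-6.91), which rose in ERKO, and Slc34a2 (7.56) and 2210407C18Rik (6.87), which rose in wild type. Each was dim in all groups but the one where it rose, so these log2 differences depend on the added 16 and give neither a measured size nor an order. Leaving out 1 array gave from 2873 without wild type PPT replicate 2 to 6735 without ERKO oil replicate 1, and 1 of the 12 arrays moved the count by more than 1.5 times.

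MOER and ERKO responses differed for 2193 probe sets, from 1078 without ERKO PPT replicate 2 to 4802 without ERKO oil replicate 1, with 8 of the 12 arrays moving the count by more than 1.5 times. The rule names Cpb1 (-8.25), Try4 (-7.87), 2210010C04Rik (-7.82), Serpinb3a (-7.42) and Smpx (-7.15). All of these but Try4 were dim outside MOER oil or ERKO PPT, so their sizes depend on the added 16 and give no order. The acinar list differed by a median of -3.25.

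Wild type and MOER responses differed for 4124 probe sets, and none of the 12 arrays moved that count by more than 1.5 times. The rule names Cpb1 (8.61), 2210010C04Rik (7.82), Slc34a2 (7.78), Try4 (7.52) and Krt4 (6.86). Again all but Try4 were dim in 3 or more of the 4 groups compared, and their sizes give no order. The acinar list differed by a median of 3.39 and the cell cycle list by 0.65.

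The acinar genes were high in both MOER oil arrays, and the smallest median log2 excess of the list over another group was 3.17. Pancreatic tissue in the pooled RNA is a candidate explanation for which this value is what would be seen. The 2 arrays of a group differed in these foreign transcripts by a median of at most 0.164 on the log2 scale, which is what RNA of 1 pool on both arrays would give, though 2 equally affected pools could give it too. A change of acinar genes in MOER hepatocytes was not tested and stays open.

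In ERKO PPT, muscle and epithelial transcripts were high, and foreign tissue in the pooled RNA was predicted to raise both lists above every other group. It did not: the lower of the 2 list medians was -0.0885, that of stratified epithelium, so the joint prediction failed. The muscle list alone gave an excess of 1.33, which is consistent with skeletal muscle in the pool, but this test was split off after the joint one had failed. The list medians over ERKO oil were 1.39 for muscle, 0.206 for stratified epithelium and 0.139 for lung epithelium. Induction of these genes in ERKO liver by PPT was not tested.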

How the results depend on the processing

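No named gene or rerun list reversed. Among the named genes 2210 comparisons with an alternative stayed on their side of the threshold, 34 lost a call and 12 gained one. Among the lists, rerun for the PPT response within each genotype alone, 1413 stayed, 71 lost a call and 28 gained one. Lists of the other contrasts were rerun only with the estimated correlation and fry. Of the counts, 185 stayed within 1.5 times and 94 moved. All 12 counts stayed within 1.5 times with the stricter filter, either pseudocount and the replicate block, which gave 931, 1089 and 360 for ERKO minus wild type, MOER minus wild type and MOER minus ERKO under oil.

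The larger share of calls changed side in several comparisons. Calls up in ERKO went from 52.83% to 42.86% with quantile normalisation and 40.45% with median centring. Wild type minus ERKO went from 46.3% to 51.51% with median centring, and the mean minus ERKO from 46.7% to 53.12% and 54.85% with the 2 scalings. ERKO minus wild type under oil went from 44.72% to 53.74% with quantile normalisation and 55.62% without the filter. The share stayed on its side under every alternative run for wild type and for both sets shared by wild type and MOER, and changed side under at least 1 alternative for each other count.

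Without the filter, ERKO minus wild type, MOER minus wild type and MOER minus ERKO under oil gave 552, 696 and 236. Quantile normalisation gave 1470 in MOER, 3500 for MOER minus ERKO, 1673 and 813 for ERKO minus wild type and MOER minus ERKO under oil, and 569 shared by wild type and MOER. Median centring gave 1716 for MOER minus wild type under oil, with 18.65% up against 37.62%. The trended robust fit gave 1609 and 777 for ERKO minus wild type and MOER minus ERKO under oil. The cause was not tested for any of these.

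With the compared arrays alone, ERKO gave 576, MOER minus ERKO 1037, ERKO minus wild type under oil 80, MOER minus ERKO under oil 60, and the set shared by wild type and MOER but not ERKO 267. The same setting raised wild type to 7923 and wild type minus MOER to 5481. The log2 changes are the same in that setting. The shifts come from taking the spread, with fewer degrees of freedom, from the compared groups alone. The SD of the log2 difference between the 2 arrays of a group was 0.341 in ERKO oil and 0.149 to 0.187 elsewhere.

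A 2-fold minimum, which by construction can only remove calls within a comparison, gave 1128 in wild type, 169 in MOER and 307 in ERKO. The 3 differences of responses gave 1290 (wild type minus ERKO), 505 (MOER minus ERKO) and 1354 (wild type minus MOER), and the mean minus ERKO 597. Under oil it gave 109 for ERKO and 180 for MOER against wild type and 80 for MOER minus ERKO, and 53 were shared, 38 of them not called in ERKO. The Cyber-T-style test gave 1129 in wild type, 170 in MOER and 290 in ERKO, 105, 181 and 77 under oil, 53 shared and 38 not called in ERKO.

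The cholesterol and fatty acid lists lost their calls with the estimated correlation: adjusted p = 0.204 and 0.204 in wild type, 0.0932 and 0.0789 in MOER, and 0.331 and 0.26 in ERKO. With fry they held their calls: 3.91e-06 and 3.91e-06, 3.11e-04 and 1.59e-04, and 0.0128 and 5.68e-04.

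Leaving out each array leaves 1 group with a lone array, assumed to vary like the others. The highest count came without ERKO oil replicate 1. It was equal without ERKO oil replicate 2 for wild type, MOER, wild type minus MOER, MOER minus wild type under oil and the shared set. The log2 changes behind those counts stay the same in these fits, so the rise comes from the changed estimate of spread. The ERKO oil pair had the widest spread (SD of 0.341). For the counts that compare ERKO oil arrays the cause was not tested. MOER ran from 437 (without MOER PPT replicate 1) to 1672, ERKO from 1200 (without ERKO PPT replicate 2) to 5346, wild type minus ERKO from 2873 (without wild type PPT replicate 2) to 6735, and MOER minus ERKO from 1078 (without ERKO PPT replicate 2) to 4802. Under oil, ERKO minus wild type ran from 230 (without wild type oil replicate 2) to 6329, MOER minus wild type from 249 (without MOER oil replicate 2) to 3332, and MOER minus ERKO from 123 (without the same array) to 2151. The mean minus ERKO ran from 1561 (without ERKO PPT replicate 2) to 5765, the shared set from 201 to 663 and the set not called in ERKO from 85 to 316, both lowest without MOER PPT replicate 1. Wild type (4026 to 7737) and wild type minus MOER (2959 to 5607) stayed within 1.5 times, both lowest without wild type PPT replicate 2. Of the 12 arrays, 6 moved the MOER count by more, 3 ERKO, 1 wild type minus ERKO, 8 MOER minus ERKO, 11, 6 and 8 the 3 comparisons under oil, 3 the mean, and 6 each shared set.

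Of the settings chosen after seeing the data, the restriction to probe sets expressed in wild type liver gave 5335 in wild type, 1000 in MOER and 3627 in ERKO. The block with the MOER PPT numbers crossed gave 1026 in MOER. All were within 1.5 times.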

Other observations

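The clock phase test was chosen only after the result was seen, while the tests of dilution, of ERKO oil replicate 2 and of the neighbours of Esr1 were written before it. Several transcripts had levels far apart between groups. H2-Ea averaged 5613 and 2629.6 in MOER oil and PPT, against 17.6 and 16.7 in wild type and 23.3 and 17.4 in ERKO. Sult2a3 averaged 47188 in wild type oil and 10152 after PPT, against 173 in ERKO oil and 259.5 in MOER oil. Nat8, an acetyltransferase gene, averaged 17.2 in wild type oil, 487 in ERKO oil and 644 in MOER oil. Adh6-ps1 averaged 5.735 in MOER oil and 594 in MOER PPT, so the 2 MOER groups differed from each other as well (at least 9.85-fold, adjusted p = 1.79e-09). The interferon-inducible gene Ifi202b (152 in MOER oil, 5.79 in MOER PPT) and the guanylate-binding gene Gbp11 (2067 and 221) were added after their values were seen. Whether the MOER groups share the genetic background of wild type, or of each other, was not tested, so neither the PPT response in MOER nor the contrasts of MOER with wild type separate background from treatment or receptor.

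Reg3b and Reg3g, which encode antibacterial lectins, rose with PPT in both mutants. Reg3b rose from 16.4 ± 7.58 to 388 ± 2.15 in MOER and from 14.3 ± 0.113 to 2738 ± 9.14 in ERKO (n = 2), and gave -0.25 (adjusted p = 0.27) in wild type. Reg3g rose at least 3.58-fold in MOER and 13.4-fold in ERKO and gave -0.03 (adjusted p = 0.9) in wild type. In ERKO PPT arrays the surfactant gene Sftpc averaged 1822 against 20.5 under oil, Krt13 2368 against 36.9, and the muscle genes Acta1 and Ckm 1813 and 1067 against 75.6 and 60.6. Sftpc, Krt13, Acta1 and Ckm were added after their values were seen.

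Fatty acid synthesis genes fell with PPT in ERKO with a list median of -0.42. Dilution of liver RNA by foreign tissue would lower secreted hepatocyte genes too, and their median change was -0.0537. The median log2 level of these genes was 13.46 in ERKO oil replicate 1 and 13.05 in replicate 2. In the 2 ERKO PPT arrays it was 13.15 and 13.19. The small change thus rests on 2 oil arrays that disagree, and the test does not decide about dilution. The fatty acid synthesis median without ERKO oil replicate 2 was -0.488, which argues against that array as the source. The median log2 change of Arntl phase genes minus that of Dbp phase genes was 1.69. A different time of day in the 2 ERKO groups may thus contribute, though how far clock phase moves the lipid genes was not measured. An effect of PPT that does not need the deleted receptor, or a receptor fragment, was not tested and stays open.

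Of 23 tested genes near Esr1, 36 neighbours before it and 50 after it being considered, 0 were called in both mutants against wild type under oil, against 293 of 13964 elsewhere (2.10%), an odds ratio of 0 (Fisher's exact p = 1). The expected number was 0.483, so 0 calls lies within chance of no excess. The number expected with passenger DNA was not computed, and the test decides nothing about passenger DNA around Esr1. The value written beforehand as evidence against it was met, and the rule that gave the verdict was changed to undecided after the result was seen.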
